A study of Homo sapiens with 4 samples.

How the data were processed

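Hep3B is a human hepatocellular carcinoma cell line. RNA immunoprecipitation sequencing (RIP-seq) pulls down a protein with an antibody and sequences the RNA that comes with it. Per the labels' protocols, cells at passages 7 to 10 were lysed for 15 min in polysomal lysis buffer, the lysate was pre-cleared with Protein G beads, part of it was kept as input, and the rest was incubated overnight with an antibody against DDX24. Beads were then added for 3 h and washed 5 times. RNA was extracted with TRIzol, and strand-specific libraries were made after ribosomal RNA depletion. The labels give 2 input libraries and 2 DDX24 RIP libraries, numbered 1 and 2 in each group, and do not say what a number marks or whether repeats came from separate cultures. The p-values therefore measure only the spread between these libraries, which may be technical. Input was the only control among these samples, and a pull-down with a non-specific antibody was not analysed here.

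The submitters' processing notes name STAR, Subread, featureCounts and DESeq2 and the build hg38, with no versions or settings. The annotation release and whether reads were counted by strand are not given in the sources used here. The values analysed were those of the authors' deposited table, which holds 1 line per gene for 58219 genes and no value per library. Its deposited mean normalized count is a signal averaged over all 4 libraries after the authors scaled each library. Fold changes were deposited on the log2 scale, each with its standard error on the same scale. The Wald score that the authors deposited equalled the log2 fold change divided by its standard error for every gene. A p-value and an adjusted p-value complete the authors' columns. Per the file headers no group is named as the numerator, and the log2 fold change was read as DDX24 RIP over input because the series describes fold enrichment over input as its negative control. If the ratio had been formed the other way, every direction given here would turn.

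The design written before the data were examined assumed counts per library and a quasi-likelihood count test. Without values per library no model was fitted here, the authors' own test was used as deposited, and no SD per group, correlation of repeats or share per library was computed. Genes with an adjusted p-value form the tested set. It holds 20997 genes. The authors' filter left the adjusted p-value empty for 7979 genes with a fold change, all with a mean normalized count under 2.47, and these stayed empty. A gene was called at an adjusted p-value under 0.05, and a further limit of a 2-fold change was applied after the test. The p-value was listed as 0 for 6 genes, below the smallest number the table could hold. Every line named a gene.

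Library depth was estimated from low values. Genes with 1 read in 1 library share 1 of 4 recurring means, which are 1 read divided by 4 times that library's size factor. Of the 10143 genes with a mean above 0 and under 5, 100% had a mean that is a sum of whole multiples of these 4 values, within 1e-06 of a read. The recovered size factors were 0.33 and 1.27 for the libraries on the higher side, read as DDX24 RIP, and 1.33 and 1.87 for those on the lower side, read as input. Which repeat has which factor is not known. Group means per gene were derived from the deposited mean and fold change, and summed to 3.32e7 normalized reads in DDX24 RIP and 2.65e7 in input. Multiplied by the size factors, these give about 1.09e7 and 4.23e7 counted reads in the DDX24 RIP libraries and 3.53e7 and 4.96e7 in the input libraries. These depths are estimates. Shares of RNA classes come from the same derived group means and have no SD.

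Transcript GC content and length came from the longest transcript of each gene in GENCODE release 29 (GRCh38), with protein-coding transcripts preferred. Gene identifiers without their version matched for 20911 of the 20997 tested genes. Coordinates are from the same annotation. Trends of the log2 fold change were fitted by lowess (span 0.3, 3 robustness rounds) on genes with a mean normalized count of at least 50 that are not mitochondrially encoded, and GC and length were fitted together by 5 rounds of backfitting. A residual was divided by the deposited standard error and tested against the normal distribution, which treats the trend as known.

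Of 28 gene lists fixed before the data were examined, 27 were tested as sets and the study's own genes formed the other. Sets were tested with cameraPR of limma (version 3.58.1, R 4.3.3), applied to the Wald scores with a preset correlation of 0.01 between genes, and Benjamini-Hochberg adjustment over the 27 lists. cameraPR compares the members of a list with all other tested genes. Other values were computed in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6.

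Genes were named by a rule fixed before the data were examined. It takes the 4 genes of the series title, the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among those called (with a mean of at least 1, and without clone-style, pseudogene, small RNA or Y-linked names); the limit of 1 was the one set for files that hold no counts, and up to 2 members per direction for each list at a mean normalized count of at least 298, which stands in for the 10 CPM of the design. Where no member passed, the 2 with the highest mean would be taken. The rule's demand that both repeats lie on the same side of both inputs could not be applied. As the genes of the second part had few reads, the same ranking at a mean of at least 298 was added after the values were seen.

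The steps were tested on simulated data made with the real standard errors. Of 200 genes changed 2-fold among 20997, the test called 50.0%, which was 100% of the 74 with a mean of at least 500 and 0% of the 73 with a mean under 50. Among its calls 5.66% were unchanged genes. Noise was drawn from the normal distribution with these standard errors taken as known. That share therefore does not test the error rate of the real comparison of 2 against 2 libraries. A planted GC trend was recovered within 0.048 on the log2 scale between 35 and 70% GC, from 12908 genes. GC content was drawn at random there, and genes left the trend only by noise of the deposited standard errors and the planted changes. The error of the trend fitted to the real genes was therefore not measured. cameraPR called 20 of 20 planted lists of 40 genes and 0 of 180 others. These lists were random draws from permuted Wald scores, with a shift added to the planted ones. Their genes were not correlated, so these counts do not show how the test behaves on lists of correlated genes.

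Alternatives run were a threshold of 0.01, no low-count filter, a mean of at least 10, tests without small RNAs and mitochondrially encoded genes, removal of the length trend, the GC trend or both, recentring on coding genes or on equal totals, a test against a fold of 2, and other forms of the set test.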

Results

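The study asked which RNAs in Hep3B cells come down with DDX24, a DEAD-box RNA helicase. The series title places DDX24 downstream of RFX8 and upstream of LAMB1 and SRC in hepatocellular carcinoma. RNA from 2 DDX24 immunoprecipitates was compared with RNA from 2 inputs of the same kind of lysate. Estimated depth was about 1.09e7 and 4.23e7 counted reads in the DDX24 RIP libraries and about 3.53e7 and 4.96e7 in the input libraries. Unless another source is named, values per gene are those of the authors' deposited table, as log2 fold change of DDX24 RIP over input ± standard error (SE) from 2 against 2 libraries, with the authors' DESeq2 adjusted p-value. The table does not name the numerator, and all directions rest on reading it as DDX24 RIP.

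DDX24 RIP and input differed for a large part of the transcriptome. The authors' deposited table lists 9562 of 20997 tested genes with an adjusted p under 0.05, 4878 higher in DDX24 RIP and 4684 lower. At least 2-fold differences were listed for 2764 higher and 2509 lower genes. Among protein-coding genes 4596 were higher and 4017 lower, of 14094 tested. Depth set which genes could be called. Of the genes with a mean normalized count of at least 500, 80.1% were called, with a median SE of 0.13, against 7.54% of those under 50, with a median SE of 1.26. The authors' scaling gave DDX24 RIP a total 1.25-fold that of input. Setting the totals equal lowers every log2 fold change by 0.33, and the split then becomes 3624 higher and 6417 lower. A test against a 2-fold change itself left 1130 higher and 616 lower genes.

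**Figure D1:**
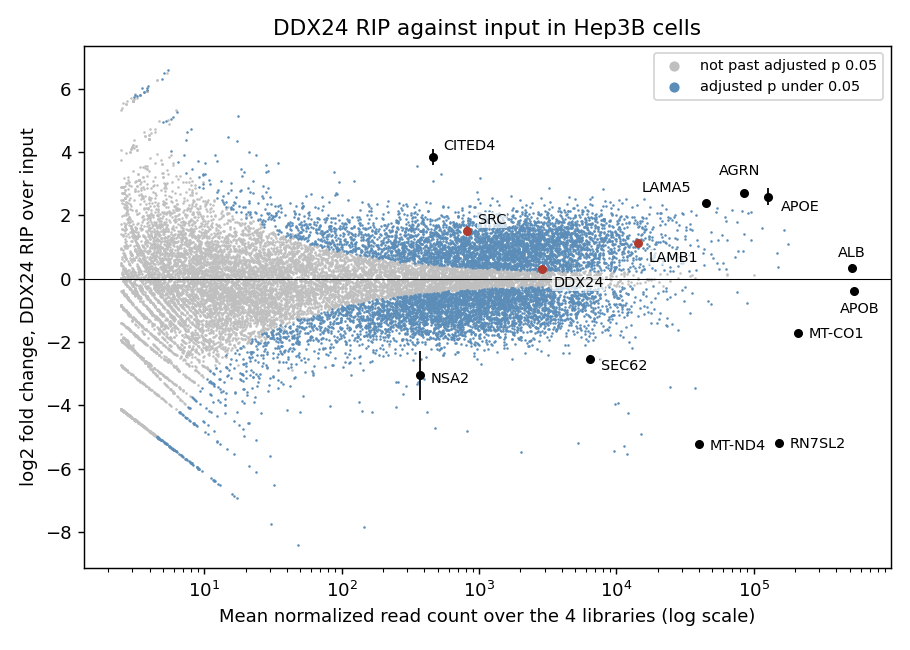
Log2 fold change of DDX24 RIP over input (vertical axis) against mean normalized read count over the 4 libraries (horizontal axis, log scale) for the 20997 tested genes, with the 9562 called genes in blue, LAMB1, SRC and DDX24 in red and other named genes in black. Bars on named genes are the deposited SE, and LAMB1 (1.11) and SRC (1.50) lie above 0 while MT-ND4 (-5.23) and RN7SL2 (-5.18) lie far below.

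LAMB1, which encodes the laminin beta 1 chain (ENSG00000091136.13, GRCh38 chromosome 7, 107923799 to 108003255, minus strand), was 2.16-fold higher in DDX24 RIP (95% interval 1.89 to 2.47) in the authors' deposited table. Its log2 fold change was 1.11 ± 0.10 (SE) at a mean normalized count of 14289, with an adjusted p of 4.44e-28. SRC, a tyrosine kinase (ENSG00000197122.11, chromosome 20, 37344685 to 37406050, plus strand), was 2.82-fold higher there (95% interval 2.27 to 3.51), with a log2 fold change of 1.50 ± 0.16 at a mean of 816 and an adjusted p of 1.42e-19. It was at 0.49 with the trend on GC content removed, and no longer called, at 0.30, with that on length removed too. The DDX24 transcript itself (ENSG00000089737.16, chromosome 14, 94048291 to 94081245, minus strand) had a log2 fold change of 0.29 ± 0.11 in the deposited table, at a mean of 2896 and an adjusted p of 0.019. That call ended once the GC trend was removed (0.18) and when the totals were set equal (-0.04). RFX8 (ENSG00000196460.12, chromosome 2, 101397361 to 101474703, minus strand), a gene of the RFX transcription factor family, had a deposited mean of 0.76, which is the value of 1 read in the shallower DDX24 RIP library, and no adjusted p. No enrichment of RFX8 could be measured at this depth. Adjusted over the list alone, LAMB1, SRC and DDX24 passed as well, but the study may have chosen these genes on these samples, so the list is not independent evidence. Among nuclear coding genes with a mean of at least 50, 17.9% had a log2 fold change as high as that of LAMB1 and 8.37% one as high as that of SRC.

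Laminins, the trimeric glycoproteins of basement membranes, rose together. Of 8 tested laminin genes 7 were higher in DDX24 RIP and none was lower in the authors' deposited table, with the same counts adjusted over the list alone. Their median log2 fold change was 1.34 (limma cameraPR, adjusted p = 8.9e-08). The list holds LAMB1, which the study may have chosen on these samples, and it was not tested without that gene. LAMA5 was highest at 2.38 ± 0.10, 5.21-fold, and LAMB2 reached 1.99 ± 0.09 in the deposited table. Chosen after their values were seen, LAMB3 was listed at 2.06 ± 0.24, LAMA3 at 1.57 ± 0.15 and LAMC1 at 0.95 ± 0.09. LAMA4 was listed at 0.28 ± 0.35, did not pass the test (adjusted p = 0.56), and fell below 0 with equal totals. In the wider list of basement membrane and matrix genes, which holds the laminins too, 26 of 38 members were higher, 2 lower and 10 not called, with the same counts of calls adjusted over the list alone and a median of 1.11 (adjusted p = 7.4e-14). AGRN, which encodes the proteoglycan agrin, stood at 2.70 ± 0.09, and HSPG2 (perlecan) and COL18A1, also chosen after their values were seen, at 2.11 ± 0.09 and 2.22 ± 0.09 in the authors' table. These sizes shrank with the GC trend removed and further with length removed too, from 2.38 to 0.82 and 0.36 for LAMA5, 2.70 to 1.05 and 0.69 for AGRN and 2.11 to 0.69 and 0.20 for HSPG2, which was then no longer called (adjusted p = 0.078). PLOD2 (-1.38 ± 0.11) and P4HA1 (-1.20 ± 0.18), enzymes that hydroxylate collagen, were the 2 members that were lower. P4HA1 was not called with the GC trend removed (-0.41), and neither was with both removed (-0.23 for PLOD2).

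Integrins, the receptors that bind laminins and other matrix proteins, went both ways in the authors' deposited table. Of 16 tested, 5 were higher and 5 lower, the same numbers adjusted over the list alone, and the set did not pass (adjusted p = 0.45), except upward with the GC trend removed (0.039). ITGB4 (2.02 ± 0.11) and ITGB5 (1.67 ± 0.09) rose, while ITGB1 (-1.48 ± 0.11) and ITGA1 (-0.76 ± 0.14) fell. ITGA1 was at 0.22 with the GC trend removed and -0.01 with both removed, not called in either. In the same 2 settings ITGB4 was at 0.66 and 0.39, ITGB5 at 1.10 and 0.96 and ITGB1 at -0.62 and -0.58. Among 41 genes of SRC signalling and focal adhesion 22 were higher and 12 lower, 22 and 14 adjusted over the list alone, with a median of 0.40 (adjusted p = 0.018). The receptor kinase ERBB2 (2.06 ± 0.10) and the adaptor BCAR1 (1.78 ± 0.11) were among the higher members in the deposited table, and the kinase YES1 (-1.75 ± 0.13) and the GTPase CDC42 (-1.46 ± 0.14) among the lower. BCAR1 was not called with both trends removed (0.16). This set's call was lost under 6 of 12 alternatives, with equal totals (adjusted p = 0.31), coding genes centred on 0 (0.050), both trends with GC content and length removed (0.58), ranks (0.17) or log2 fold changes (0.30) in the set test, and a preset correlation of 0.05 (0.17).

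Among genes with a mean normalized count of at least 298, the deepest losses from DDX24 RIP were of mitochondrially encoded transcripts, copies of them and 7SL RNA. All 13 mRNAs of the mitochondrial genome were lower in the authors' deposited table, also adjusted over the list alone, with a median log2 fold change of -4.70 (cameraPR adjusted p = 4.2e-98). MT-ND2 stood at -5.52 ± 0.15, 46.0-fold lower, and MT-ATP6 at -5.44 ± 0.36, 43.3-fold lower, with an SE 3.48 times that typical of its mean. MT-CO1, named after its value was seen, was the least depleted at -1.71 ± 0.09 and the most abundant, with a mean of 208699. Mitochondrial genes overlap each other (MT-ATP6 and MT-ATP8, MT-ND4 and MT-ND4L) and have near-identical nuclear copies such as MTATP6P1 (-5.46 ± 0.19), so the reads of single genes are uncertain. The set test preset a low correlation between genes, and members that overlap may be more correlated than that. The size of its p-value for this list rests on that setting and is not read as strength of evidence. Under the 11 alternatives that could test the list, the adjusted p ran from 2.8e-254 (GC trend removed) to 5.2e-08 (ranks in the set test). Of 16 mitochondrial tRNAs 12 were lower. RN7SL2 and RN7SL3, copies of the RNA of the signal recognition particle that share reads, stood at -5.18 ± 0.12 and -3.93 ± 0.12 in the deposited table. In the list of small structured RNAs, which holds RN7SL2 and RN7SL3 and otherwise mostly genes with few reads, 9 of 11 members were lower and none higher, with the same counts adjusted over the list alone and a median of -3.37 (adjusted p = 6.5e-08).

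By class, the group means derived from the authors' deposited table put nuclear protein-coding genes at 98% of normalized reads in DDX24 RIP and 93.8% in input. Mitochondrially encoded genes took 0.35% against 2.5%, and 7SL RNA 0.032% against 1.21%. Long non-coding and other genes took 1.18% against 1.97%, with 169 higher and 473 lower of 4409 tested. An exact permutation test of 2 against 2 libraries cannot go below p = 0.33 and no share per library was available, so these shares carry no test.

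Small RNAs of the nucleus had few reads. Of 164 snoRNAs, guides of ribosomal RNA modification, 2 were higher, 17 lower and 145 not called (2 and 10 adjusted over the list alone; adjusted p of the set test = 0.11). SNORD3B-1 was listed at -1.54 ± 0.14 and SNORA73B at -0.79 ± 0.18 in the authors' table. Among 17 scaRNAs, guides in Cajal bodies, 3 were lower and none higher (2 lower adjusted over the list alone; adjusted p of the set test = 0.11), with SCARNA6 at -1.23 ± 0.23. Both sets passed when log2 fold changes replaced the Wald scores, with an adjusted p of 1.5e-05 for snoRNAs and 6.1e-07 for scaRNAs. The scaRNAs also passed downward on ranks (0.028) and with the GC trend removed (0.039), but not with length removed too (0.58). The snoRNAs turned upward with both trends removed, without passing (adjusted p = 0.32), with a median of 0.55 and 104 of 164 above the trend. The fit of 2 trends was not checked in simulation for RNAs as short as SNORA73B (204 nucleotides) or SCARNA6 (265), so these changes with length removed are uncertain. Of 14 long non-coding RNAs listed in advance as held in the nucleus, 3 were higher and 8 lower, also over the list alone (adjusted p of the set test = 0.064). Where the members of this list lie in Hep3B cells was not measured. OIP5-AS1 (-1.28 ± 0.12) and JPX (-1.71 ± 0.22) fell, and KCNQ1OT1 (0.57 ± 0.15) and PVT1 (0.55 ± 0.20) rose in the deposited table. PVT1 lost its call under 5 alternatives, among them a threshold of 0.01 and removal of the length trend (0.36), KCNQ1OT1 with equal totals (0.25) and with both trends removed (0.36), and OIP5-AS1 with the GC trend removed (-0.27). The set passed downward without the low-count filter (adjusted p = 0.027) and after both recentrings (0.015 and 0.044). With the GC trend removed it did not pass and turned upward (adjusted p = 0.69), with a median of 0.07 and 7 of 13 members above the trend. MALAT1, chosen after its value was seen, was at -0.76 ± 0.10, and at 0.07 with the GC trend removed. Hosts of snoRNAs went both ways, with 3 of 18 higher and 7 lower under either adjustment (adjusted p of the set test = 0.41). SNHG3 (-1.39 ± 0.11) and SNHG16 (-1.32 ± 0.14) were lower, and SNHG12 (1.12 ± 0.16) and SNHG7 (1.14 ± 0.13) higher, but with the GC trend removed SNHG12 was not called (0.35) and SNHG7 turned to -0.39. Whether antisense genes such as OIP5-AS1 were counted by strand is not stated, so their reads are uncertain.

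Transcripts of the translation machinery lay below input as groups. Of 79 cytosolic ribosomal protein genes 17 were higher, 46 lower and 16 not called (18 and 51 adjusted over the list alone), with a median of -0.47 (cameraPR adjusted p = 0.00046). RPL39 (-1.70 ± 0.14) and RPL21 (-1.48 ± 0.13) fell furthest among those with a mean of at least 298 in the authors' deposited table, while RPL3 (1.29 ± 0.10) and RPS16 (0.96 ± 0.10) rose. Mitochondrial ribosomal proteins, made from nuclear genes, showed 14 higher and 41 lower of 78 (15 and 41 over the list alone), a median of -0.45 and an adjusted p of 0.018. MRPL50 (-2.31 ± 0.20) and MRPL47 (-1.87 ± 0.18) fell, and MRPS34 (1.37 ± 0.12) and MRPL4 (1.26 ± 0.13) rose, but the latter 2 were at -0.06 and -0.20 with the GC trend removed, where neither was called. With length removed too MRPS34 was called again at 0.29, while MRPL4 (-0.05) and MRPL47 (-0.40) were not called. Of 20 genes in a list of translation factors and other genes with a 5' terminal oligopyrimidine tract, 5 were higher and 12 lower (6 and 12 over the list alone). Their median was -0.66, with a cameraPR adjusted p of 0.018. That median was -0.39 with the GC trend removed and -0.33 with length removed too. EIF3E (-1.82 ± 0.13) and NPM1 (-1.61 ± 0.14) fell in the deposited table, and EEF2 (1.58 ± 0.09) and EEF1D (1.30 ± 0.10) rose, the last of which was at 0.0071 with the GC trend removed (adjusted p = 0.98). The ribosomal protein genes have processed pseudogenes that can share their reads. These 3 sets lost their calls when log2 fold changes replaced the Wald scores (adjusted p of 0.32, 0.30 and 0.42) and at a preset correlation of 0.05 (0.079, 0.23 and 0.11), and the last of them on ranks as well (0.064).

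Chaperones of the endoplasmic reticulum and parts of its secretory pathway showed 14 of 47 genes higher and 27 lower (14 and 28 adjusted over the list alone), with a median of -0.46 and an adjusted p of 0.00046. SEC62, a translocon subunit, stood at -2.53 ± 0.12 and SRP14, a protein of the signal recognition particle, at -2.21 ± 0.16 in the authors' deposited table, against 1.30 ± 0.10 for COPG1 and 1.23 ± 0.09 for P4HB. This call ended with log2 fold changes in the set test (adjusted p = 0.30) and with the GC and length trends both removed (adjusted p = 0.11). The median of the list was -0.18 with the GC trend removed and -0.12 with both removed. Zinc finger genes named ZNF were mostly lower, with 250 of 478 lower and 81 higher (257 and 84 over the list alone), a median of -0.79 and an adjusted p of 0.00046, which ended at a preset correlation of 0.05 (adjusted p = 0.17). Their median was -0.23 with the GC trend removed and -0.26 with length removed too. ZNF254 (-2.10 ± 0.21) and ZNF714 (-2.08 ± 0.18) fell and ZNF837 (2.18 ± 0.16) and ZNF579 (2.06 ± 0.15) rose in the deposited table, but ZNF837 was not called with the GC trend removed (0.34).

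Glycolytic genes were higher as a group. Of 20 tested, 13 were higher, 1 lower and 6 not called, with the same calls adjusted over the list alone, a median of 0.94 and an adjusted p of 4.9e-05. PFKL, a subunit of phosphofructokinase, stood at 1.78 ± 0.11 and the lactate transporter gene SLC16A3 at 1.64 ± 0.11 in the authors' deposited table, while LDHA was the lower member at -0.72 ± 0.14. Much of this followed GC content, as the median of the list was 0.27 with the GC trend removed (adjusted p = 0.028) and 0.23 with length removed too (0.029). LDHA was no longer called with the GC trend removed (-0.27), nor SLC16A3 with both removed (0.15). Hepatocyte secreted proteins included APOB and ALB, the 2 genes named here with the highest means. Of 45 tested, 20 were higher and 14 lower, also over the list alone, and the set did not pass (adjusted p = 0.095). It passed upward without the low-count filter (0.027) and with the GC and length trends removed (0.0026). APOE (2.59 ± 0.26) and C3 (1.52 ± 0.09) rose, and FGB (-1.86 ± 0.17) and CP (-1.11 ± 0.12) fell. Chosen after their values were seen, ALB was at 0.33 ± 0.13 and APOB at -0.39 ± 0.11 in the deposited table, and APOB was at 0.11 and CP at -0.17 with the GC trend removed, neither called. ALB was not called at a threshold of 0.01, with the length trend removed (0.11), with coding genes centred (0.23) or with equal totals (0.01).

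Other lists split in both directions and did not pass the set test as run on the deposited values. DEAD/DEAH helicases, the family of DDX24, had 19 of 50 higher and 12 lower (20 and 12 adjusted over the list alone, adjusted p = 0.095). The set passed upward without the low-count filter (0.027), with the GC trend removed (0.00078) and with the length trend removed too (0.0026). DHX37 (1.79 ± 0.11) and DHX30 (1.73 ± 0.10) rose and DDX21 (-1.05 ± 0.12) and DHX40 (-0.99 ± 0.19) fell in the authors' deposited table, but the latter pair were not called with the GC trend removed (-0.28 and -0.19). Of 72 ribosome biogenesis factors 26 were higher and 27 lower (26 and 28 over the list alone, adjusted p = 0.60), with BOP1 at 2.35 ± 0.11 and NCL and UTP3 at -1.83 ± 0.10 and -1.77 ± 0.18. Innate RNA sensing had 12 of 31 higher and 4 lower (13 and 4 over the list alone, adjusted p = 0.27), with IKBKE (1.48 ± 0.15) and IRF3 (1.42 ± 0.11) against EIF2AK2 (-1.63 ± 0.17) and TRAF6 (-0.81 ± 0.22). IRF3 (0.23) and TRAF6 (-0.14) were not called with the GC trend removed. Targets of p53 had 7 of 21 higher and 8 lower under either adjustment (adjusted p = 0.42), with FDXR at 1.57 ± 0.22, RRM2B at -1.66 ± 0.21 and MDM2 at -1.63 ± 0.11. With the GC trend removed FDXR (0.16) and RRM2B (-0.46) were not called and BBC3, listed at 1.36 ± 0.20, turned to -0.45. With both trends removed the p53 set passed downward (adjusted p = 0.044).

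Cell cycle genes had 14 of 40 higher and 18 lower under either adjustment (adjusted p = 0.85), with CDT1 (1.53 ± 0.12) and MCM2 (1.48 ± 0.09) against CDK1 (-1.44 ± 0.14) and CCNA2 (-1.17 ± 0.14) in the authors' deposited table. With the GC trend removed CDT1 (0.07) and CDK1 (-0.29) were not called, and with length removed too both were at -0.03. Immediate early and AU-rich genes had 13 of 32 higher and 7 lower under either adjustment (adjusted p = 0.28), with JUND (2.12 ± 0.14) against CXCL1 (-0.87 ± 0.16). JUND was not called with the GC trend removed (0.32) or with both removed (0.34), nor CXCL1 with both removed (-0.15). JUNB (1.44 ± 0.12) fell to -0.02 with the GC trend removed, and CXCL8 (-1.69 ± 0.13) turned to 0.14 with both trends removed. Replication-dependent histones had 9 of 65 higher and 12 lower (7 and 10 over the list alone, adjusted p = 0.60), with HIST1H1E at 1.20 ± 0.13, not called with the GC trend removed (0.13) but called with both removed (0.63), and HIST2H2BE at -0.81 ± 0.17. Their near-identical copies make reads of single genes uncertain. With the GC trend removed the histone set passed downward (adjusted p = 3.4e-09), with a median of -0.61 and 16 of 64 members above the trend, but not with length removed too (0.58). HIST1H1C, listed at 0.81 ± 0.12, was at -0.04 with the GC trend removed but called at 0.54 with both removed, and HIST1H2BF, at -0.74 ± 0.20, was at -0.15 and 0.29, not called in either. Median, mean and set test differed in sign for the ribosome biogenesis, p53, cell cycle, histone and immune marker lists, so no direction is given for their deposited values.

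Markers of cell types other than hepatocytes were mostly not tested or not called in this cell line. Of 20 immune markers 5 were tested, with 2 higher and 1 lower under either adjustment (adjusted p = 0.84). These were CD14 (1.47 ± 0.21), CD74 (0.35 ± 0.14) and LYZ (-1.70 ± 0.15) in the authors' deposited table, and CD74 was not called at a threshold of 0.01, with the length trend removed (0.16) or after either recentring, and was called lower with the GC trend removed (-0.61). Of 14 fibroblast markers 7 were tested, with 4 higher and 1 lower under either adjustment (adjusted p = 0.27). PDGFRB (1.41 ± 0.12) and TAGLN (1.15 ± 0.18) rose and LUM (-0.96 ± 0.19) fell, but LUM was at 0.25 with the GC trend removed, where the set passed upward (adjusted p = 0.039) and TAGLN was not called (0.40). The set also passed upward on log2 fold changes (adjusted p = 0.035). Of 14 endothelial markers 12 were tested and 1 was higher, VWF at 0.55 ± 0.22. It was not called at a threshold of 0.01, with equal totals (0.22), with coding genes centred (0.45) or with the GC trend removed (-0.39), and was called lower with both trends removed (-0.74). None of the endothelial markers passed when adjusted over the list alone (adjusted p of the set test = 0.72).

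**Figure D2:**
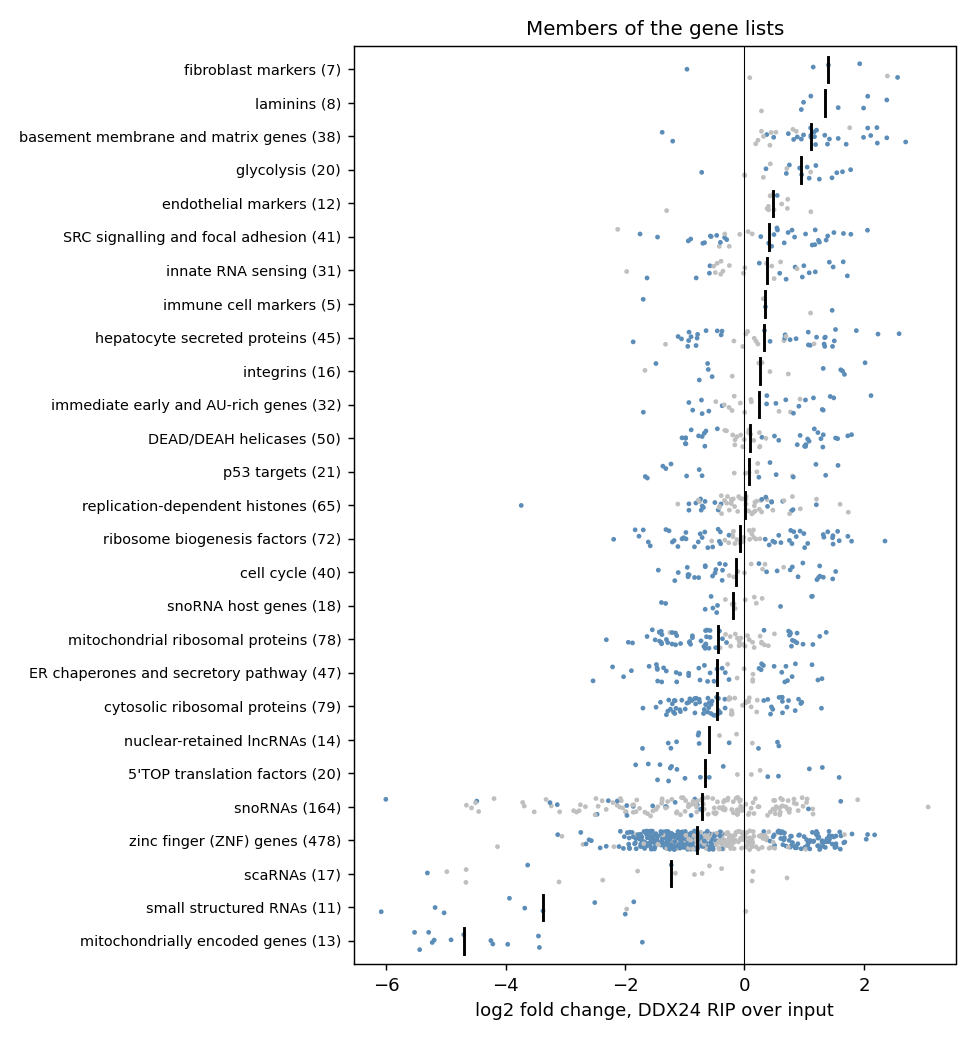
Log2 fold change of DDX24 RIP over input (horizontal axis) for each tested member of the 27 gene lists, with called members in blue, others in grey, the number tested in brackets and the list median as a black bar. Mitochondrially encoded genes (median -4.70) and small structured RNAs (-3.37) lie lowest, and laminins (1.34) and basement membrane and matrix genes (1.11) lie near the top.

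At a mean normalized count of at least 298, a limit added after the values were seen, the genes with the highest log2 fold changes in the authors' deposited table were CITED4 (3.84 ± 0.26), a transcriptional coactivator, PCSK1N (3.55 ± 0.24), PDF (3.31 ± 0.26), the peptide deformylase of mitochondria, TMEM160 (3.19 ± 0.17) and CTU1 (3.07 ± 0.24), a tRNA-modifying enzyme. GLTPD2 (2.87 ± 0.13), NR2F6 (2.84 ± 0.12), SOX18 (2.74 ± 0.16), AGRN (2.70 ± 0.09) and SAC3D1 (2.62 ± 0.13) followed. These are GC-rich transcripts (62.2 to 74.5% GC), and with the GC trend removed they were between 0.79 (GLTPD2) and 2.07 (PDF). The lowest were mitochondrial transcripts. Among the lowest nuclear genes were NSA2 (-3.05 ± 0.77, with an SE 3.57 times that typical of its mean, and not called, at -1.61, with the GC trend removed), a ribosome assembly factor, and RBM7, SEC62, MOB4, VMA21, RRP15, TMEM106B, RPL36AL and C8orf4, the latter 8 between -2.57 and -2.44 in the deposited table.

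With the lower limit fixed in advance, the rule named genes with few reads. The largest positive values in the authors' deposited table belonged to WNT5B, HAGLROS, ARAP1-AS2, ODF3L2, ATP13A4, PSAPL1, RAET1E-AS1, CABP1, CYS1 and RENBP, from 6.60 ± 2.13 for WNT5B at a mean of 5.44 to 4.63 ± 1.67 for RENBP at a mean of 7.42. The largest negative values were those of ZIM2-AS1 (-6.52 ± 1.73 at a mean of 13.1), GDF5, IL7, RALYL, TP63, CDC37L1-AS1, LINC00441 and GFI1B (-5.40 ± 2.03 at a mean of 5.99), besides MT-ND2 and MT-ATP6. Apart from the mitochondrial pair these rest on a few reads, where 1 group can be close to 0, so the fitted sizes are not read as folds. Of the 10 higher genes 8 (those other than WNT5B and RAET1E-AS1) lost their call at a threshold of 0.01 and with the GC trend removed, and ODF3L2 and ATP13A4 also without the low-count filter and after both recentrings. Among the lower genes TP63, LINC00441 and GFI1B lost theirs at 0.01, and IL7 and RALYL with both trends removed.

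Enrichment followed the base composition of the transcript. Across 14068 nuclear coding genes the log2 fold change of the authors' deposited table rose with the GC content of the longest transcript, with a Spearman rho of 0.78, and 0.86 among the 1211 genes with a mean of at least 5000. These are correlations across genes, which are not independent replicates. The tenth of genes with the lowest GC content, 30.2 to 38.7%, had a median of -1.14, with 78.6% called lower and 0.14% higher. The tenth with the highest, 62.4 to 76.0%, had a median of 1.49, with 76.4% called higher and 0.50% lower. Among genes with a mean of at least 50 the GC trend removed 69.5% of the variance of the log2 fold change. With length the relation was weak, with a rho of -0.09, and it turned to 0.30 once the GC trend was removed.

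Relative to genes of the same GC content, LAMB1 stayed well above the trend and SRC less so. At 49.5% GC the trend gave 0.11 for LAMB1 and left 1.0 of its log2 fold change of 1.11 in the authors' deposited table, a remainder reached by 2.53% of coding genes with a mean of at least 50. With length also removed 0.81 was left for LAMB1, reached by 4.66% of these genes. For SRC, at 59.3% GC, the trend gave 1.01 and left 0.49, reached by 18.3% of genes, and with length also removed 0.30 was left (adjusted p = 0.17). Laminins kept a median of 0.91 above the GC trend, with 8 of 8 above it, and basement membrane and matrix genes 0.65, with 32 of 38 above it. Cytosolic ribosomal proteins lay at a median of -0.59 against the trend, mitochondrial ribosomal proteins at -0.47 and mitochondrially encoded mRNAs at -3.85. With length removed too these medians were 0.66 for laminins, 0.50 for basement membrane and matrix genes, -0.27, -0.24 and -3.41 for the latter 3 lists. With the GC trend removed 5594 genes were called. Of the calls made in the table for genes with a GC value, 3651 kept their direction and a call, 621 were called in the opposite direction and 5276 were no longer called.

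**Figure D3:**
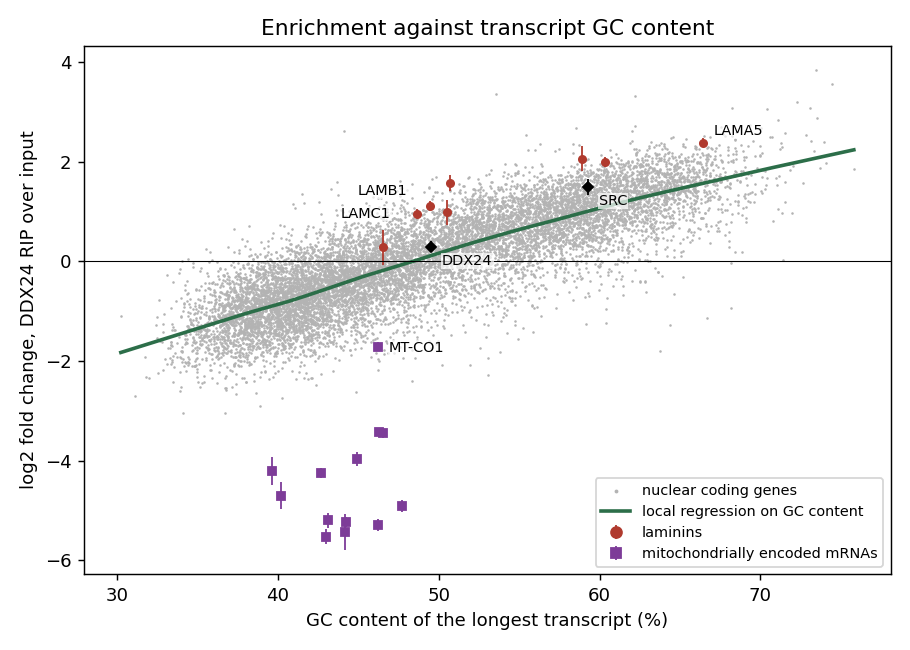
Log2 fold change of DDX24 RIP over input (vertical axis) against GC content of the longest transcript in percent (horizontal axis) for nuclear coding genes with a mean normalized count of at least 50, with a local regression line in green, laminins in red, mitochondrially encoded mRNAs in purple and SRC and DDX24 as black diamonds, bars being the deposited SE. All 8 laminins lie above the line and all 13 mitochondrially encoded mRNAs below it.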

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

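Removal of the GC trend (alone or with that of length), recentring, the filter at a mean of 10, and the set tests on ranks, on log2 fold changes and at a preset correlation of 0.05 were chosen after seeing the data. No paired analysis was possible because the table holds no values per library, although input and DDX24 RIP share repeat numbers. For the same reason the alternatives fixed before the data were examined that need such values, namely other normalizations, a limit on counts per library, other count tests, the replicate block with and without length, pseudocounts, leaving out each library, an estimated set correlation, fry and correlations of repeats were not run. Tests without small RNAs and mitochondrially encoded genes kept the authors' library scaling. Depth limits what was called below a mean of 50, where the SE of most genes exceeds 1 on the log2 scale, and 1 DDX24 RIP library was 3.87 times shallower than the other.

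The count of 9562 called genes fell to 5594 with the GC trend removed and 5010 with both trends removed, and stayed within 1.5 times under the other 7 alternatives. Genes at least 2-fold higher fell from 2764 to 382 and 406 with these removals, 1571 with equal totals and 1130 in a test against a fold of 2. Those at least 2-fold lower went from 2509 to 921 and 568, 4041 and 616. The share of calls that were higher moved from 51.0% to 52.4% at an adjusted p of 0.01, 49.3% without the length trend, 46.2% with coding genes centred and 36.1% with equal totals. The loss of 2-fold calls under equal totals follows from the shift of 0.33 itself.

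LAMB1 kept its direction and call under every alternative run (0.78 to 1.18). SRC did except with both trends removed, at 0.30. DDX24 kept 0.29 but no call at 0.01, and stood at 0.18 (GC trend removed), 0.19 (coding genes centred), -0.0096 (both trends removed) and -0.035 (equal totals). Of 11 list calls, 6 held at a preset correlation of 0.05. Those for laminins, basement membrane and matrix genes, glycolysis, mitochondrially encoded genes and small structured RNAs held in every alternative that could test them. The rho with length was -0.12 at a mean of at least 298 and 0.30 with the GC trend removed, and that with GC was 0.85 at that limit.

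Some sets that did not pass did so under an alternative (helicases, hepatocyte secreted proteins, histones, p53 targets, integrins, fibroblast markers, nuclear RNAs, snoRNAs and scaRNAs). Of 156 named genes, 32 lost their call but kept their sign with the GC trend removed and 37 with both trends removed. With the former these included NSA2, PVT1, OIP5-AS1, SNHG12, HIST1H1E, HIST1H2BF, DDX21, DHX40, ZNF837, P4HA1, CP, IRF3, TRAF6, FDXR, RRM2B, LDHA, CDT1, CDK1, EEF1D, JUND, CXCL8 and TAGLN. With the latter they included NSA2, MRPL47, KCNQ1OT1, PVT1, DHX40, ZNF837, PLOD2, P4HA1, ITGA1, BCAR1, CP, TRAF6, FDXR, RRM2B, SLC16A3, LDHA, CDK1, EEF1D, JUND, JUNB, CXCL1, APOB, HSPG2, MALAT1 and SRC.

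With the GC trend removed, signs reversed for MRPS34 (-0.057), MRPL4 (-0.20), SNHG7 (-0.39), HIST1H1C (-0.036), ITGA1 (0.22), BBC3 (-0.45), JUNB (-0.017), CD74 (-0.61), LUM (0.25), VWF (-0.39), APOB (0.11), NEAT1 (0.31, from -0.13 with no call) and MALAT1 (0.075). With both trends removed they did for MRPL4 (-0.050), SNHG7 (-0.42), HIST1H2BF (0.29), BBC3 (-0.41), CDT1 (-0.026), CXCL8 (0.14), CD74 (-0.46), LUM (0.38) and VWF (-0.74). LAMA4 was at -0.043 with equal totals. Beyond the values given, the cause of these changes was not tested.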

Other observations

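All tests weighed in this part were chosen after the results were seen. Genes far from the GC trend at a mean normalized count of at least 298 were also picked after their values were seen. Among those above it were, from values of the authors' deposited table, PCDH7 (2.06 above the trend) and TPBG (1.92), both encoding cell surface proteins, and HNRNPA0 (1.83), an RNA-binding protein. THBS1, the matrix protein thrombospondin 1, had a mean normalized count of 85654 and lay 1.69 above the trend. FBN1, which encodes fibrillin 1, lay 1.35 above it, NID1 (nidogen 1) 0.87 and FN1 (fibronectin) 0.70. ALB, with a GC content of 41.3%, lay 1.08 above it.

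Among the genes furthest below the trend were FKBP2 (3.18 below, residual of -3.18), a chaperone of the endoplasmic reticulum, and YBX1 (-2.74), which encodes a major mRNA-binding protein and stood at -2.28 ± 0.12 in the authors' deposited table. MIF (-2.71), PPDPF (-2.63), SH3BGRL3 (-2.34), the mitochondrial chaperonin gene HSPE1 (-2.26), PFDN2 (-2.16), DBI (-2.13) and RPL36 (-2.08) were others. These are mostly short transcripts, from 677 nucleotides for PFDN2 to 1661 for SH3BGRL3, and with the length trend also removed FKBP2 was at -2.81, YBX1 at -2.51 and PFDN2 at -1.58.

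Some abundant genes had an SE far above that of genes with a like mean in the authors' deposited table, as a wide spread within a group would give. Of 9514 genes with a mean of at least 298, 21 had an SE over 2.5 times the median of their neighbours. The ratio was 5.53 for MT-RNR2 (-3.28 ± 1.20), 4.61 for SPTAN1 (0.90 ± 0.45, adjusted p = 0.094), 3.77 for NDUFA5 (-2.42 ± 0.69), 3.57 for NSA2, 3.48 for MT-ATP6 and 3.25 for FAM171A2 (2.38 ± 0.39).

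The rise of enrichment with GC content could come from the RNA that DDX24 holds or from the making of the libraries. It could also come from other steps that only the immunoprecipitate went through, such as contact with beads and antibody. Length does not account for it, since the partial rho given length was 0.80 across 14068 coding genes, and neither do low counts, since rho was 0.86 among the 1211 genes with a mean of at least 5000. A recovery of fragments that depends on GC content and differs between immunoprecipitate and input needs the trend in non-coding RNA as well, and rho was 0.66 among 912 long non-coding RNAs. A preference of the complex for GC-rich RNA allows that too. These 2 cannot be told apart here, nor from binding to the beads or to any antibody. Every immunoprecipitate belongs to 1 group, and no pull-down with another antibody was analysed here.

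Laminin transcripts may be held by DDX24 beyond what base composition gives, a hypothesis found and tested on the same data. The fitted trend on GC content of the longest transcript does not account for all of their enrichment. Their median stayed at 0.91 with that trend removed (8 genes, 95% bootstrap interval 0.77 to 1.09, cameraPR adjusted p = 5.9e-10). With the length trend removed too it was 0.66 (0.36 to 0.93, cameraPR adjusted p = 5.3e-06). The intervals resample genes, so they measure neither the spread between libraries nor the error of the fitted trends. The longest transcript need not be the one sequenced. Recovery of all transcripts of secreted proteins stays open. Hepatocyte secreted proteins had a median of 0.26 with both trends removed (45 genes, interval 0.077 to 0.55; cameraPR adjusted p = 0.0026), and the intervals overlap. Binding to the beads or to any antibody was not tested.

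Mitochondrially encoded mRNAs had a median of -4.70, and neither GC content nor length accounts for it, since nuclear coding genes of the same GC range (39.6 to 47.7%) had a median of -0.50 over 3866 genes (lowest -2.74) and those of the same length range (207 to 1812 nucleotides) a median of 0.18 over 1762 (lowest -3.04). The log2 fold change of MT-CO1, -1.71, lay within those of both groups of nuclear genes. The other 12 mRNAs, at -3.43 or lower, lay below the lowest of either group. For the 7SL genes (-5.18 and -3.93) GC content does not account for the loss, as nuclear coding genes of their GC range (62.2 to 62.7%) had a median of 1.37 over 129. At a mean of at least 50, 11 other small RNAs of 200 to 400 nucleotides, some of them copies of 7SK, had a median of -0.49. The lowest of them, at -3.63, lay above both 7SL genes. These values argue against short length alone, though they cover few genes. A general loss of structured RNAs stays open. The 9 other tested small structured RNAs, most with few reads, had a median of -2.51 (lowest -6.08), with 7 called lower. That DDX24 does not meet RNA inside mitochondria could explain the loss of their mRNAs, but it could not be tested.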
